A study of Mus musculus with 4 samples.

How the data were processed

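RNA was measured from brain tissue of male C57BL/6J mice aged 9 weeks, taken 6 h after permanent occlusion of the middle cerebral artery with an intraluminal filament and an injection of saline into the ventricle, per the labels. Each of 4 two-color arrays on 1 slide carried ischemic tissue in one dye and the corresponding healthy tissue in the other. Of these arrays, 2 held core tissue (replicates 1 and 2) and 2 held penumbra tissue (replicates 3 and 4). Ischemic RNA was in Cy5 on core replicate 1 and penumbra replicate 3, and in Cy3 on core replicate 2 and penumbra replicate 4. The labels speak of 3 mice per group but not of pooling, and they do not say whether healthy tissue came from the other hemisphere or from other animals.

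The deposited scanner files held spot intensity in both dyes, written by Agilent Feature Extraction 11.0.1.1, per the file headers and the submitters' processing notes. The deposited series table held log10 ratios, which equalled the log10 of Agilent's processed Cy5 signal over its processed Cy3 signal to within 5e-06 on every array, so their scale and direction were known. The column medians of that table were -0.0195 and 0.00509 for core replicates 1 and 2, and -0.0181 and -0.00874 for penumbra replicates 3 and 4. No slide or scan batch could be tested, because there was 1 slide and 1 scan session.

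Median spot signals were corrected for local background with normexp (offset 50) and normalized by loess within each array in limma 3.58.1 (R 4.3.3), with control spots and spots with outlier marks at weight 0. The plan fixed before the data were examined named mean signals, but the files held 0 columns of mean signal, so medians were used. Ratios were turned to ischemic over healthy on every array. Control spots, and spots marked by the scanner software as non-uniform or as population outliers, were left out, and spots of one probe were averaged. A probe entered a region's comparison if it was well above background on both arrays in at least 1 of the 2 tissues. For a gene with several probes, the brightest stood for the gene; among the genes named below, none had probes in one region more than 1 log2 unit apart. Scanner files gave accessions and no gene symbols. Of 41174 probes, 23374 were named through an accession table of assembly GRCm38.p6 without version numbers, and the others kept their accession. This gave 33269 features, of which 16535 had a symbol. Tables were handled in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9.

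Depth on an array is signal over background. Median spot signals were 192 to 225.5 in Cy3 and 284 to 310 in Cy5, against median local backgrounds of 64 to 66 in Cy3 and 70 to 71 in Cy5. Between 76.1% and 79.4% of spots were well above background, and 0 spots were saturated. The number of arrays limits the precision.

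Nothing in the labels says that the 2 arrays of a region held different RNA extracts, so each dye-swapped pair was counted as 1 replicate and calls rest on no p-value. An alternative, limma over arrays, gave p-values that measure only the spread between arrays. Its calls asked for a low adjusted p-value and also for at least 1 log2 unit. A gene was called by size: at least 2-fold in the mean of the pair and at least 1.5-fold in the same direction on each array. Errors are the SD between the 2 arrays, which includes dye bias that cancels in the mean of the swapped pair. The labels do not say whether this SD holds any spread between extracts, and it is not read as spread between animals. The difference between core and penumbra was called where it was at least 1 log2 unit and both core arrays lay on the same side of both penumbra arrays. For exchangeable arrays, chance alone would meet the second condition, without the first, in 33.3% of genes. These arrays are not fully exchangeable, since each core array shares its dye orientation with 1 penumbra array. Healthy core was compared with healthy penumbra, and ischemic core with ischemic penumbra, on single-channel values after loess and Aquantile, within each dye, by the same 2-fold and 1.5-fold rule.

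The naming rule, fixed before the data were examined, took the 6 highest and 6 lowest called genes of each region and of the difference between regions, and 4 and 4 for each comparison of pieces, among genes measured on both sides. It also took up to 4 called members of each gene list per region, or, where fewer than 2 were called, the brightest uncalled members up to 2 in all. A gene named for one region could be given for the other. Names that were accessions or clone names were counted and not named. Not every gene that the rule took is reported here. Adcyap1 was named in any case, because the treatment protocol mentions PACAP38, its product.

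In all, 36 gene lists were fixed before the data were examined, with 550 entries, of which 516 were on the array by symbol. A list's median log2 ratio was set against 10000 random lists of the same size matched on intensity in 20 bins. A list was said to stand apart above percentile 97.5 or below percentile 2.5, as a description of these arrays and not a test. Lists with fewer than 5 measured members were only described.

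The steps were tested on simulated data. Of 50 spots changed 4-fold, 98% were called in the simulated core and 86% in the simulated penumbra. For 3-fold changes these shares were 92% and 80%, and for 2-fold changes 8% and 12%, with a 2-fold change measured at a median of 0.88 and 0.91 log2. No unchanged spot was called (0 in each). Almost all of the simulated spread was dye bias, the same on both arrays, which cancels in the mean of the swapped pair. The simulation therefore says little about false calls, or about the shares called, under noise that differs between arrays. Of 200 random lists, 13 in the core and 11 in the penumbra stood apart by chance, and of 50 lists shifted by 0.2, 49 and 47 were found. Alternatives covered background correction, Agilent's processed signals, the series table, median centring, filters on dim probes, the mean over probes, the size threshold, each array left out, and limma over arrays with and without a dye coefficient.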

Results

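Gene expression in the mouse brain was measured 6 h after permanent occlusion of the middle cerebral artery, a model of stroke. The core is the tissue with the deepest loss of blood flow, and the penumbra is the zone around it. Each region was measured on 2 dye-swapped two-color arrays, counted as 1 replicate, with ischemic tissue set against the corresponding healthy tissue. There was no replicate check of ischemia itself, so genes are called by size, and every error below is the SD between the 2 arrays. All ratios are relative to the median of all genes. A scaling to spike-in control transcripts, chosen after the data were seen, would lower every ratio by 0.48 log2 in the core and 0.46 in the penumbra, and list medians smaller than that would turn negative. Between 76.1% and 79.4% of spots were well above background in each dye of each array. Median SDs between arrays were 0.10 log2 in both regions, but 0.61 in the core and 0.59 in the penumbra for genes with a log2 intensity of 16 or more.

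Which genes differ between ischemic and healthy core was the first comparison. Among the highest ratios in ischemic core were those of single heat shock, immediate early and chemokine genes. Hspa1a, an inducible heat shock protein of the HSP70 family, had a log2 ratio of 4.54 ± 0.53 (23.2-fold). Npas4, a neuronal activity-dependent transcription factor, had 4.19 ± 0.10 (18.3-fold), and Ccl4, a chemokine that attracts monocytes and other leukocytes, had 3.59 ± 0.02 (12.0-fold). Fos, a subunit of the AP-1 transcription factor, had 3.34 ± 0.32, and Atf3, a stress-induced transcription factor, had 3.21 ± 0.22. Hspb1, a small heat shock protein, had 1.96 ± 0.11. Hspa1b had 3.66 ± 0.25; it and Hspa1a are nearly identical in sequence, so their separate values are uncertain.

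Of 24537 features, 76 were called higher in ischemic core and 0 lower. With the sign of 1 array left unturned, which leaves dye bias and array noise, 8 features passed. Ratios of the 2 turned arrays correlated across genes at r = 0.42, and genes are not independent replicates. Of all features, 98.1% lay within 0.5 log2 of 0. Agilent's processed signals, which carry no added offset, gave 230 higher and 15 lower, with log2 ratios of 4.52 for Ccl4, 3.49 for Ccl3 and 1.84 for Il1b. The spike-in scaling gave 31 higher and 30 lower and ended the calls of Bdnf, Dusp1, Dusp4, Gadd45b, Gadd45g, Il1b, Inhba, Nfkbiz, Nptx2 and Ptgs2; without core replicate 1, 83 features were higher and 12 lower, and the calls of Dusp1 and Nptx2 ended.

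Immediate early genes, transcribed within minutes of a stimulus, had a median of 1.04 in the core, and 14 of 24 members were called higher. Egr2, a zinc finger transcription factor, had 3.13 ± 0.07. All 24 members had a mean above 0. Phosphatases and other feedback regulators of MAP kinases had a median of 0.61 with 3 of 13 members called, among them Dusp6 at 1.66 ± 0.01, Dusp1 at 1.13 ± 0.23 and Dusp4 at 1.09 ± 0.07. Heat shock proteins and chaperones had a median of 0.40 with 4 of 16 called, the fourth being the co-chaperone Dnajb1 at 1.67 ± 0.03.

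Some inflammatory genes were also called higher in ischemic core. Of 18 measured chemokines 5 were called higher, with a list median of 0.54, or 1.25 with processed signals. Ccl3 had 2.84 ± 0.01, Cxcl1, a neutrophil attractant, 1.67 ± 0.04, and Ccl2, a monocyte attractant, 1.67 ± 0.21. Of 12 cytokines 1 was called, Il1b at 1.02 ± 0.01, with a median of 0.31 over the list. NF-kappaB feedback genes had a median of 0.39 with 1 of 12 called, Nfkbiz at 1.36 ± 0.08. Of 9 neutrophil markers 3 were called, with a median of 0.46, or 2.41 with processed signals and 2.11 over those well above background in both tissues: S100a9 at 2.49 ± 0.06, its partner S100a8 at 2.39 ± 0.00, and Retnlg at 2.11 ± 0.06. Monocyte and macrophage markers had a median of 0.23 with 1 of 11 called, the lipopolysaccharide co-receptor Cd14 at 1.53 ± 0.11. Microglia markers had a median of 0.00 and 0 of 17 were called. Endothelial activation genes had a median of 0.16 with 1 of 9 called, the prostaglandin synthase Ptgs2 at 1.12 ± 0.03.

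Growth factors and neurotrophins had a core median of 0.36 with 3 of 15 called: Bdnf at 1.24 ± 0.01, Inhba, a subunit of activin, at 1.07 ± 0.07, and the synaptic pentraxin Nptx2 at 1.06 ± 0.25. Matrix and proteolysis genes had a median of 0.41 with 2 of 17 called, Ccn1 at 1.78 ± 0.09 and Adamts1 at 1.54 ± 0.07. The p53 and cell death list had a median of 0.25 with 2 of 19 called, Gadd45g at 1.46 ± 0.16 and Gadd45b at 1.24 ± 0.15. Among neuropeptides, 1 of 14 was called, Nts (neurotensin) at 2.01 ± 0.08, and the list median was -0.02. Adcyap1, which encodes PACAP, had 0.69 ± 0.19 and was not called.

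Other lists stood apart in the core with 0 called members. These were the unfolded protein response (median 0.27), reactive astrocyte genes (0.30), cholesterol synthesis (0.22), hypoxia response (0.21), oligodendrocyte markers (0.20), striatal markers (0.15), circadian clock genes (0.15) and antioxidant genes (0.09). Below matched lists lay meningeal fibroblast markers (-0.18), oligodendrocyte precursor markers (-0.13), astrocyte markers (-0.08) and synaptic genes (-0.06). In all, 20 lists stood above and 4 below matched random lists. Several of these small shifts lost their place with 1 array left out, where dye bias no longer cancels. On each array alone, the hypoxia, clock, striatal, oligodendrocyte and cholesterol medians still lay above 0. Without core replicate 1, the hypoxia list fell to percentile 96.1, the clock list to 91.4 and the striatal list to just under the upper bound, and the synaptic median went to 0.02; without core replicate 2, the oligodendrocyte list fell to percentile 89.8 and the cholesterol list to 95.5. The antioxidant and astrocyte lists lost their place without either array and with the mean over probes, and the synaptic and astrocyte lists with median centring.

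**Figure D1:**
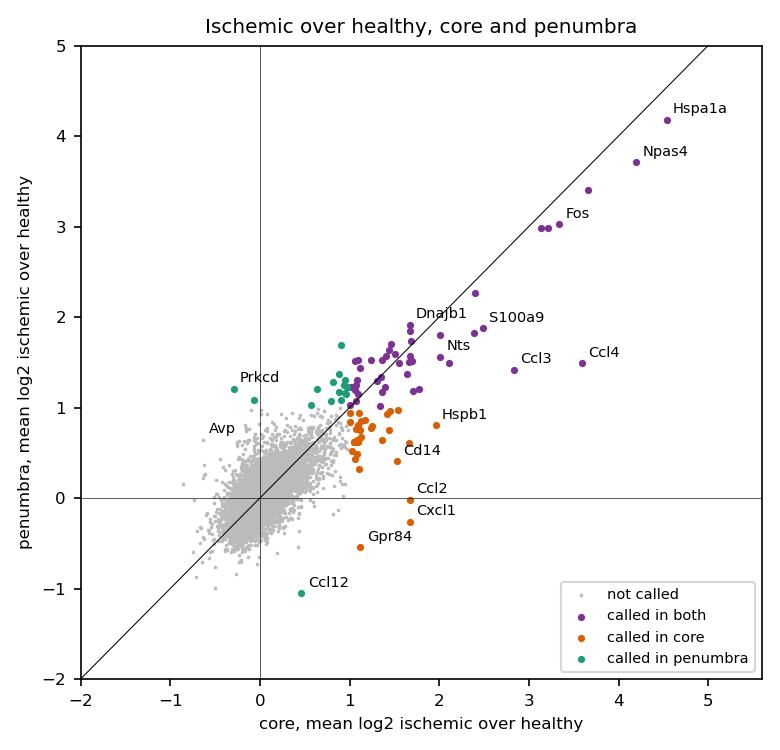
Mean log2 ratio of ischemic over healthy tissue in the core (x axis) against the penumbra (y axis), 1 point per gene, colored by where the gene was called; the line marks equal ratios. Hspa1a and Npas4 lie far up near the line, and Ccl4, Ccl2, Cxcl1 and Gpr84 lie below it.

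In the penumbra, among the highest ratios were those of single heat shock and immediate early genes. Hspa1a had a log2 ratio of 4.18 ± 0.31 (18.1-fold), Npas4 3.71 ± 0.04 (13.1-fold) and Hspa1b 3.41 ± 0.13. Fos had 3.02 ± 0.31, Atf3 2.99 ± 0.07 and Egr2 2.99 ± 0.14. Ccl12, a chemokine, was the only feature called lower by the rule in ischemic than in healthy penumbra, at -1.05 ± 0.11.

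Of 24926 features, 60 were called higher and 1 lower, and 6 passed with 1 sign unturned. The turned arrays correlated across genes at r = 0.50. Agilent's processed signals gave 189 higher and 30 lower, and the spike-in scaling 29 higher and 41 lower, ending the calls of Ccl3, Ccn1, Dusp14, Inhba, Nptx2, Prkcd and Ptgs2. Without penumbra replicate 3, 75 were higher and 11 lower. The call of Ccl12 ended without penumbra replicate 4, that of Dusp14 with median centring, with the mean over probes and without penumbra replicate 3, and that of Inhba with median centring.

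Immediate early genes had a penumbra median of 1.12 with 13 of 24 called higher, and all 24 lay above 0 on both arrays. MAP kinase feedback genes had a median of 0.41 with 3 of 13 called, Dusp4 at 1.53 ± 0.01, Dusp6 at 1.51 ± 0.10 and Dusp14 at 1.07 ± 0.20. The heat shock list had a median of 0.46 with 3 of 16 called, including Dnajb1 at 1.92 ± 0.12. Of 9 neutrophil markers 3 were called, with a median of 0.25, or 1.07 with processed signals: S100a9 at 1.88 ± 0.23, S100a8 at 1.82 ± 0.01 and Retnlg at 2.82-fold (SD 0.16 log2). Growth factors had a median of 0.34 with 3 of 15 called, Bdnf at 1.52 ± 0.05, Nptx2 at 1.20 ± 0.24 and Inhba at 1.07 ± 0.08. Other called list members were Gadd45g at 1.71 ± 0.20 (list median 0.14), Nts at 1.56 ± 0.14 (-0.10), Ptgs2 at 1.44 ± 0.03 (0.08) and Ccn1 at 1.20 ± 0.04 (0.28).

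Chemokines and cytokines as lists did not stand apart in the penumbra. Of 17 measured chemokines, Ccl4 at 1.49 ± 0.10 and Ccl3 at 1.42 ± 0.09 were called higher and Ccl12 lower; the list median was -0.02, and its sign changed with median centring, with no filter on dim probes and without penumbra replicate 4. The 12 cytokines had a median of -0.05 (percentile 15.5, or 1.2 with median centring) with 0 called. Choroid plexus and ependymal markers had a median of 0.58, and 8 of 8 were above 0 on both arrays. Meningeal fibroblast markers had a median of 0.38, with 10 of 10 above 0 on both arrays. Thalamic and hypothalamic markers had a median of 0.22, and 1 of 12 was called, Prkcd, a protein kinase C isoform enriched in thalamus, at 1.21 ± 0.11. Adcyap1 had 0.28 ± 0.15 and was not called.

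Also above matched lists in the penumbra, with 0 called members, were the unfolded protein response (median 0.27), cholesterol synthesis (0.26), reactive astrocyte genes (0.21), hypoxia response (0.20), oligodendrocyte markers (0.19), monocyte and macrophage markers (0.14) and antioxidant genes (0.12). Below them lay striatal markers (-0.13) and synaptic genes (-0.12). In all, 17 lists stood above and 2 below. Without penumbra replicate 3 the p53 list fell to percentile 96.1 and the synaptic list rose to 9.63, and the antioxidant list lost its place without either array.

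For lists with few called members, the naming rule took their brightest members, and 52 such genes were called in neither region. Their means ran from -0.45 (Kl, a choroid plexus gene) to 0.51 (Hspa5, an endoplasmic reticulum chaperone) in the core, and from -0.36 (Dbp, a clock gene) to 0.63 (Clic6) in the penumbra. In 31 of them in the core and 25 in the penumbra the mean was smaller than the SD between arrays. Of the 52, 12 in the core and 11 in the penumbra had an SD over 0.5 log2, bright neuronal and glial genes among them. Part of this SD is dye bias, which has opposite signs on the 2 turned arrays and cancels in their mean. The mean Cy5 over Cy3 ratios of the 2 pairs correlated across genes at r = 0.808, so the SD is not the error of the mean. The synaptic gene Nrgn had 0.08 ± 1.81 in the core and -0.10 ± 1.42 in the penumbra, the myelin gene Mbp 0.19 ± 0.67 and 0.15 ± 1.02, and the metallothionein Mt2 0.08 ± 1.27 and 0.14 ± 1.20. Smaller SDs were those of the cholesterol synthesis gene Hmgcs1, at 0.32 ± 0.10 and 0.44 ± 0.09, and of the interferon-regulated factor Irf1, at 0.27 ± 0.02 and 0.22 ± 0.01.

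**Figure D2:**
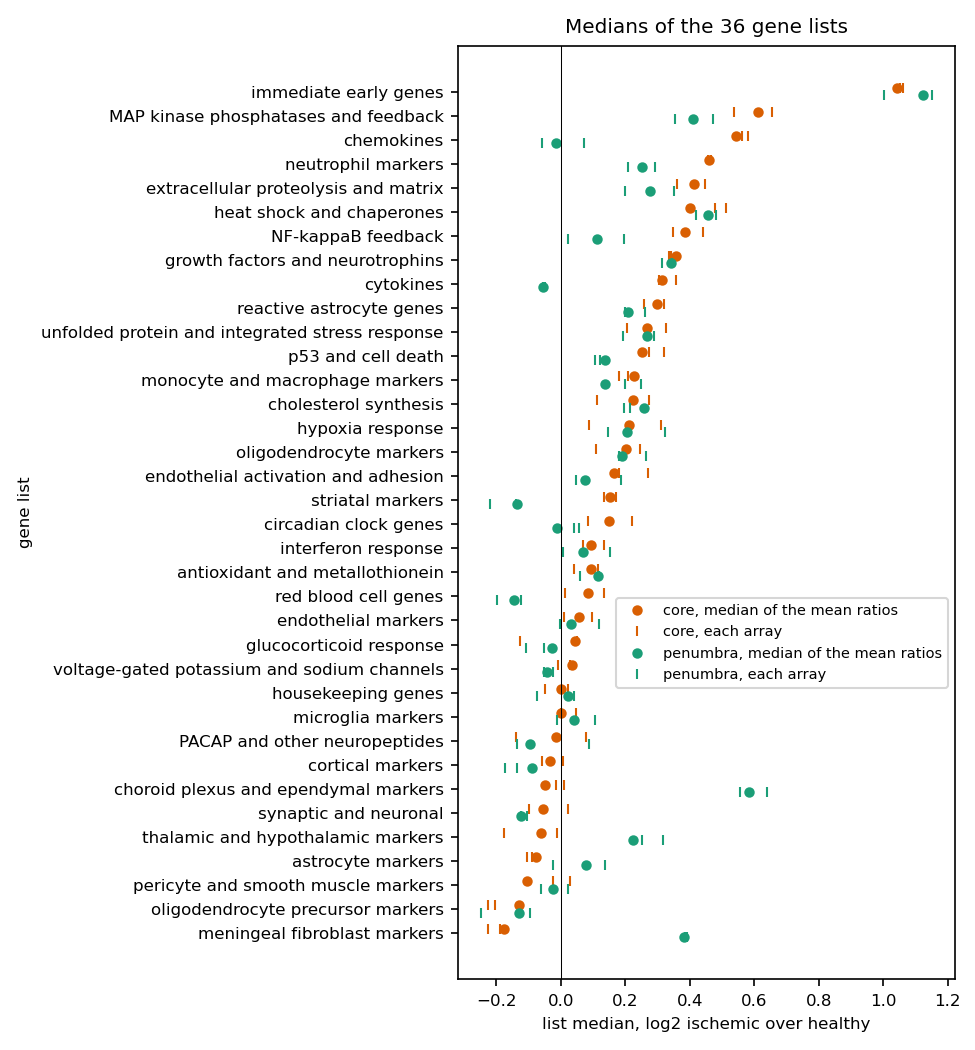
Median log2 ratio of ischemic over healthy tissue (x axis) of the 36 gene lists (y axis) in core and penumbra; circles are medians of the mean ratios and ticks are medians on each array. Immediate early genes lie near 1.04 and 1.12, while chemokines lie at 0.54 in the core and -0.02 in the penumbra.

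How the core and penumbra profiles differ is the question in the title of the series. Among the largest differences by the rule were those of chemokines. The ischemic over healthy ratio of Ccl4 was higher in the core by 2.10 log2, that of Cxcl1 by 1.93, Ccl2 by 1.69, Ccl12 by 1.52 and Ccl3 by 1.42. Gpr84, a receptor of myeloid cells for medium-chain fatty acids, was higher by 1.67, Hspb1 by 1.16 and Cd14 by 1.11. Lower in the core were Prkcd at -1.50, Avp (vasopressin) at -1.29 and the G protein-coupled receptor Mrgprf at -1.02. Of the genes lower in the core, Prkcd is enriched in thalamus, and 2 of 12 thalamic and hypothalamic markers passed the rule in this direction. None of the differences of the genes lower in the core was told apart from one in the make-up of the dissected pieces.

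By the rule, 15 of 25251 features differed, 10 higher and 5 lower in the core, and 7 of the 10 were chemokines. No test across animals was possible with 1 replicate per region. An alternative, limma over arrays, which measures only the spread between arrays, called 7 features, or 15 with a dye coefficient. These limma calls also asked for at least 1 log2 unit. Without that cut, 7 features passed by adjusted p-value, or 824 with the dye coefficient. The call of Mrgprf ended without core replicate 2 and without penumbra replicate 3. Leaving out an array moved the balance of directions: 12 were higher and 23 lower without core replicate 1, 17 and 8 without core replicate 2, 13 and 11 without penumbra replicate 3, and 13 and 17 without penumbra replicate 4. Agilent's processed signals gave 93 higher and 86 lower, with differences of 2.89 for Ccl4, 2.57 for Cxcl1 and 2.35 for Gpr84. Of the features called higher, 45 were called in both regions, where independent lists would share 0.188. Another 31 were called in the core alone, of which 6 passed the difference rule, and 15 in the penumbra alone, of which 2 passed. Of the 76 called in the core, 73 had a mean above 0 in the penumbra. Mean ratios of the regions correlated across genes at r = 0.73.

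Healthy core was set against healthy penumbra to give the baseline difference of the dissected pieces. Choroid plexus and striatal genes were far lower in the healthy core piece. Ttr (transthyretin, a product of choroid plexus) differed by -6.47 ± 0.02 log2 (mean and SD over the 2 dyes), Ecrg4 by -3.99 ± 0.10, the potassium channel subunit Kcne2 by -3.40 ± 0.11 and Clic6 by -3.37 ± 0.07. Higher in healthy core were Akr1c18 at 1.91 ± 0.04, the sodium channel subunit Scnn1a at 1.90 ± 0.04, Tcap at 1.83 ± 0.09 and Tspan11 at 1.80 ± 0.02.

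Of 24896 features, 282 were called, 78 higher and 204 lower in healthy core. Striatal markers had a median of -1.85 with 12 of 14 called lower, and choroid plexus markers a median of -2.94 with 7 of 8 called lower. Oligodendrocyte markers had a median of -0.79. Cortical markers had a median of 0.46 with 3 of 16 called higher, and meningeal markers 0.86 with 2 of 10 called higher. Of 17 chemokines, 5 were called lower in healthy core, and the list median was -0.49. Ccl4 differed by -1.80 ± 0.04, Ccl12 by -1.66 ± 0.15, Cxcl1 by -1.50 ± 0.21, Ccl2 by -1.41 ± 0.06 and Ccl3 by -1.37 ± 0.06, and Gpr84 by -1.56 ± 0.11. With Cy5 alone the rule called 461, and with Agilent's processed signals 853, which put Ttr at -8.47, Kcne2 at -4.66 and Tspan11 at 2.52.

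Ischemic core set against ischemic penumbra differed in choroid plexus genes as well. Ecrg4 differed by -4.59 ± 0.18, Kcne2 by -4.35 ± 0.01, Clic6 by -4.04 ± 0.12 and the keratin Krt18 by -3.95 ± 0.12. Higher were Tcap at 2.37 ± 0.02, Ly6d at 2.09 ± 0.05, Akr1c18 at 2.06 ± 0.07 and Tspan11 at 1.87 ± 0.02. Over 18 measured chemokines the median difference was 0.23, at percentile 99.97 of matched lists, opposite in sign to healthy tissue. Of those called lower in healthy core, Ccl4 differed by 0.30 ± 0.13, Ccl2 by 0.28 ± 0.06, Cxcl1 by 0.43 ± 0.08, Ccl3 by 0.05 ± 0.02 and Ccl12 by -0.14 ± 0.10. Hspb1 was higher by 0.99 ± 0.06, against -0.16 ± 0.03 in healthy tissue.

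Of 24877 features, 334 were called, 107 higher and 227 lower in ischemic core. Of these, 54 higher and 155 lower were also called in the healthy comparison, where independent lists would share 0.34 and 1.89. Both comparisons use the same 4 arrays, so part of this overlap may come from shared spots. Across genes the comparisons correlated at r = 0.891. With Cy3 alone the rule called 544, and with Agilent's processed signals 1036, which put Kcne2 at -5.73, Krt18 at -5.02 and Tspan11 at 2.91. The mean over probes put Clic6 at -3.40.

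**Figure D3:**
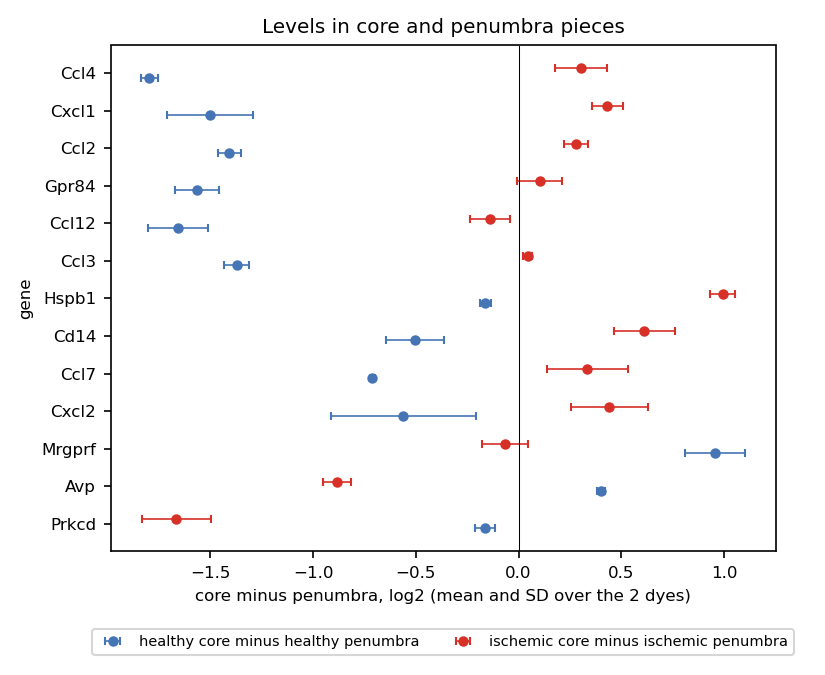
Core minus penumbra difference (x axis, log2, mean and SD over the 2 dyes) in healthy and in ischemic tissue for the 13 genes with a symbol that passed the difference rule (y axis). The chemokines and Gpr84 lie below 0 in healthy tissue and between -0.14 and 0.44 in ischemic tissue; Cxcl2 in healthy core was not well above background.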

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

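The tests in this part were all chosen after the results were seen. Several genes and lists moved in opposite directions in the core and the penumbra on all 4 arrays. They were picked by direction and not by size, so very small ratios are among them, such as those of S100a10 (-0.04 in the core against 0.05 in the penumbra). The share of genes and lists that would meet this by chance was not worked out. Opposite direction alone is therefore no evidence of opposed responses in the regions. The differences between regions were not tested across animals, since each region has 1 replicate. Over arrays, limma measures only the spread between arrays, and it called 7 features as differing between regions, or 15 with a dye coefficient. Both counts also asked for at least 1 log2 unit.

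Differences of the ischemic over healthy log2 ratio, core minus penumbra, were 1.93 for Cxcl1 (1.67 against -0.26), 1.67 for Gpr84 (1.12 against -0.54) and 1.52 for Ccl12 (0.46 against -1.05). They were -1.50 for Prkcd, -1.29 for Avp (-0.64 against 0.65), -1.02 for Mrgprf (-0.86 against 0.16), -0.88 for Kl, -0.76 for Zic1, -0.58 for Scnn1a, -0.55 for Igf2 and -0.49 for Gpr17. Small differences were 0.55 for Tcap, 0.31 for Hbb-bt, 0.21 for Hba-a1 and -0.09 for S100a10. Among list medians, cytokines differed by 0.37, striatal markers by 0.29, thalamic and hypothalamic markers by -0.29 and meningeal fibroblast markers by -0.56. Set against matched random lists, the median of the gene differences lay above the range for cytokines (0.34) and striatal markers (0.32). It lay below the range for thalamic and hypothalamic (-0.34) and meningeal fibroblast markers (-0.69). These lists were picked for opposite medians in the 2 regions, which favored this outcome, and the random lists were not. The ranking describes these arrays and is no test across animals.

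The chemokine difference between regions was set against 3 explanations. Other differences in the make-up of the healthy pieces, such as those in choroid plexus and striatal markers, were not tested as a cause. The 7 chemokines that passed the difference rule differed between healthy core and healthy penumbra by a median of -1.41 and between the ischemic pieces by 0.30; the rule that chose them favors a low healthy value, and over 17 measured chemokines the healthy median was -0.49. The healthy median of all measured chemokines was -0.31 or lower under all scalings and in each dye, and below matched lists each time, which argues against array scaling or dye. Microglia markers were also lower in healthy core, 16 of 17 of them and below percentile 2.5 of matched lists, but only by a median of -0.10 with quartiles of -0.18 and -0.07, which argues against more microglia in the healthy penumbra piece as the whole cause. An inflammatory response in the healthy penumbra tissue itself may account for the pattern, but the lists did not decide it. Of 3 lists chosen for this, 2 lay below percentile 2.5 there, cytokines and NF-kappaB feedback genes but not immediate early genes. Nor did interferon response genes (percentile 79.1), endothelial activation genes (75.55), monocyte and macrophage markers (44.9), reactive astrocyte genes (21.4) or neutrophil markers (9.585). With 1 replicate per region this stays open, as does a difference between the regions.

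Choroid plexus markers were higher in ischemic than in healthy penumbra by a median of 0.58. All 8 lay above 0 on both arrays, which argues against dye bias or array noise. Their ratios spanned 0.43 to 0.71 with an SD over markers of 0.10, as a larger amount of choroid plexus in the ischemic penumbra piece would give, so unequal dissection is a candidate explanation. Higher transcription of these genes after ischemia was not tested. Meningeal fibroblast markers and thalamic and hypothalamic markers were also higher in ischemic penumbra, by medians of 0.38 and 0.22. Prkcd differed between core and penumbra by -0.16 in the healthy pieces and by -1.665 in the ischemic pieces. Whether unequal dissection gave these differences was not tested.

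The spike-in control spots, left out of the comparisons except as an alternative scaling, carried more signal relative to all other genes in ischemic than in healthy RNA. The median shift of 10 transcripts was 0.48 log2 in the core and 0.46 in the penumbra, and 10 of 10 lay above 0 in each region. The shift stayed between 0.38 and 0.48 under every normalization, so it did not depend on which of them was used. All of them set the bulk of genes near 0, so they could not show whether that centring gave the shift. Unequal amounts of spike-in or RNA between labelling reactions could give it, since the spike-ins' Cy5 over Cy3 ratio also differed by 0.39 between the region pairs. A lower share of messenger RNA in ischemic tissue was not tested.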

How the results depend on the processing

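Spike-in scaling was chosen after seeing the data; the other alternatives were fixed beforehand. No analysis paired by replicate was possible because the groups share no replicate numbers. Arrays of the 2 regions were matched only by dye, in the comparisons of pieces and in limma with a dye coefficient. Agilent's processed signals and the series table hold the same ratios and gave 245 genes in the core, 219 in the penumbra and 179 differing between them, against 76, 61 and 15; all 76, 61 and 15 remained among them. With Aquantile they gave 853 for the healthy and 1036 for the ischemic pieces, against 282 and 334. A 1.5-fold minimum gave 224 (211 higher, 13 lower), 229 (220 and 9), 110 (39 and 71), 857 and 998 for these 5 comparisons, and a 3-fold minimum gave 27, 17 and 4 for the first 3, by construction. limma over arrays gave 7 genes differing between regions, and 15 with a dye coefficient, both with at least 1 log2 unit asked for. Leaving out 1 array gave 93 to 95 genes in the core, 78 to 86 in the penumbra and 24 to 35 differing between regions. There was then 1 array fewer to pass, and dye bias no longer cancelled in the mean. These 2 effects were not told apart. With 1 dye, 378 to 461 healthy and 416 to 544 ischemic differences passed. Where no construction is named, the cause was not tested. Spike-in scaling lowers every ratio by 0.48 log2 in the core and 0.46 in the penumbra, and then 50.8% and 41.4% of calls were higher, against 100% and 98.4%; for list percentiles it changes nothing by construction and was not run. Processed signals had 86.3% higher in the penumbra and 52.0% in the difference, against 98.4% and 66.7%. Between 20 and 26 lists stood apart in the core and 19 to 21 in the penumbra, against 24 and 19. Called values of named genes kept their direction in all 776 recomputed cases, and 19 moved by over 1.5 times. In many of these cases the direction could not change by construction. The filters leave a value as it is, the calling rules already ask for the same direction on each array, and the series table repeats the processed signals. Signal over background limits which genes can be measured. With no filter on dim probes, 76 and 61 were called again. This cannot show whether low signal limits the calls, since the offset added to the signals draws ratios of dim probes toward no change. Among list medians, those of chemokines in the core and of neutrophil markers in both regions moved by over 1.5 times, up to 3.86 times, with processed signals.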

Other observations

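Several lists lay within the range of matched random lists in both regions. In core and penumbra, the median log2 ratios were 0.09 and 0.07 for interferon response genes, 0.06 and 0.03 for endothelial markers, 0.04 and -0.04 for voltage-gated potassium and sodium channels, -0.03 and -0.09 for cortical markers, and -0.10 and -0.02 for pericyte and smooth muscle markers. Microglia markers had 0.00 and 0.04, both with a sign that changed with median centring. Housekeeping genes had 0.00 and 0.02, a sign that changed with the scaling. Glucocorticoid response genes had 0.05 and -0.03, and the core sign changed with processed signals, with the series table and without core replicate 1. Under some alternative, the sign also changed for channels and cortical markers in the core, endothelial markers in the penumbra, and pericyte markers in both. Red blood cell genes, with 4 measured members, had 0.09 and -0.15.

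Of the lists that stood apart in 1 region, chemokines, cytokines and endothelial activation genes are given above. The others had these medians in the other region: circadian clock genes -0.01, astrocyte markers 0.08, oligodendrocyte precursor markers -0.13 and NF-kappaB feedback genes 0.11 in the penumbra, and choroid plexus markers -0.05 and thalamic and hypothalamic markers -0.06 in the core.

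Some lists within the range of matched lists left it under an alternative. Interferon response genes in the core (percentile 97.45) went above it with no background correction, with processed signals and the series table, with the mean over probes and without core replicate 1. Without penumbra replicate 3, interferon response, endothelial activation and NF-kappaB feedback genes in the penumbra went above it, the last also with median centring. Cortical markers in the penumbra went below it without either array. Pericyte and smooth muscle markers in the core went below it with either other filter and with the mean over probes. Without core replicate 1, neuropeptides and thalamic and hypothalamic markers in the core went below it, the latter also with no filter. Oligodendrocyte precursor markers in the penumbra went below it with no background correction, with processed signals and the series table, and without penumbra replicate 3.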
